A study of Sus scrofa with 4 samples.

How the data were processed

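Transcript levels were measured in slices of ileum, the last part of the small intestine, from suckling piglets aged 16 days. The piglets had Yorkshire × Landrace dams and Duroc sires, and total RNA was purified on columns and treated with DNase, per the labels' protocols. Each of 4 RNA samples was labelled with Cy3 and hybridised to 1 pig array with 45220 spots, so that every array had 1 colour. All 4 arrays lay on 1 slide and were scanned in 1 run, so that neither slide nor scan differed between groups. Per the labels, 2 samples were pools of 2 piglets with low weight gain and 2 samples were pools of 3 piglets with high weight gain. The samples of each group carry the letters a and b. The design text speaks instead of piglets with the lowest and highest weight at birth, and the sample labels were followed here.

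The labels do not say whether a and b were separate pools or repeat arrays of 1 pool. The p-values therefore measure only the spread between these arrays, which may be technical, and variation between piglets was not measured. If a and b shared 1 pool, each group holds 1 independent sample. The 32 probes in each group that were spotted 5 times and lay well above background on both arrays gave a check. Their a minus b differences had an SD of 0.227 (log2) in the low-gain group, 1.28 times that expected from the repeat spots, and of 0.232 in the high-gain group, 1.53 times that expected.

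The deposited scanner files hold spot intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal is an intensity on a linear scale after the scanner software's background treatment, and the median signal and local background are pixel values, per the file headers. The authors also deposited a table of log2 values for the same arrays. Its processing is not given in the sources used here. Its scale was found by comparison with the scanner values, with slopes between 1.00 and 1.01 on log2 processed signal and correlations across spots with the same array from 0.984 to 0.999. Its values were not centred per gene. Its column medians were 5.62 and 5.59 for low-gain arrays a and b, and 5.67 and 5.60 for high-gain arrays a and b. It was used only as an alternative.

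Of the spots, 43803 were not controls, and they represented 43603 probes. The processed signal was put on a log2 scale and the array's 75th percentile over non-control spots was subtracted. Spots with an outlier flag were left out, spots of 1 probe were averaged, and 48 probes with a missing value were dropped. A probe was tested if it lay well above background, by the scanner's flag, on both arrays of at least 1 group, which left 33265 probes. No spot was saturated. The number of arrays limits the precision of every value.

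Gene names came only from RefSeq accessions in the array design, matched without versions to an NCBI gene table of Sscrofa11.1. Of 5779 probes with such an accession, 5461 matched, and they named 2389 genes. This was 12.5% of probes. Another 7535 probes carried Ensembl transcript identifiers, 13875 carried TC identifiers, 5135 carried only a probe name and 11279 carried other identifiers, and all of these stayed unnamed here. The files name no genome build, so no coordinates are given. Where a gene had several tested probes, the probe with the highest mean signal over the 4 arrays stood for it, which gave 2158 genes. Closely related genes (granzymes, serum amyloid A, lysozyme and histocompatibility genes) can cross-hybridise, and their values are uncertain in that respect.

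Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, as low gain minus high gain, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Errors given with log2 changes are standard errors of that fit, with 2 arrays per group. A probe that was not well above background on either array of a group has only a bound there. It is given as "at least" a fold, from the bright group's mean over the dim group's mean, each dim value raised to the lowest signal well above background on its array. Such a bound is a ratio of means and carries no error, so it is not a confidence limit. Gene lists for cell types and pathways, 39 in number, were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives not described as added. Lists with at least 4 measured members, 36 in all, were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. With an estimated correlation, camera uses the residual degrees of freedom of the fit, 2 here, so that test has little power. Members were also counted with p-values adjusted over the list alone. The rule named the 12 genes with the largest change in each direction, taking those past the test first, and up to 4 members of each list. Mostly, 4 members are given only for lists with an unadjusted camera p under 0.05, and 2 for the others. This cut was not in the rule and depends on the results. The values of 2 list members are not reported here.

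The fit was tested on 20 simulated data sets of 33265 probes with the spread of the real arrays, taken as equal on all 4 arrays. In each, 100 probes were changed at each size. The fit recovered 1.2% of log2 changes of 1, 60.8% of changes of 2 and 81% of changes of 3, and 2.06% of its calls were false. With a prior variance that followed signal intensity, the same simulations gave 45.6%, 78.2% and 90.5%, with 5.64% false calls. In the real data, 6117 probes had an unadjusted p under 0.05 in limma, far more than were changed here, so these rates need not carry over. In simulated lists of 12 genes, 4.05% of 2000 unchanged lists had an unadjusted p under 0.05, and all 10 lists shifted by 0.7 were found. The simulated genes were independent, so the preset correlation itself was not tested.

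The alternatives were quantile normalisation, median centring, normexp background correction (offset 50), no filter on dim probes, a filter requiring signal on all 4 arrays, the intensity trend, the letter as a block, the deposited log2 table, leaving out each array, the mean over a gene's probes and the estimated correlation. Normexp was run on the median signal because the mean signal planned for it is not a column of the files used here. Figures were drawn with matplotlib from the tabulated values.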

Results

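Gene expression in the ileum was compared between piglets of low and of high weight gain at 16 days of age, a comparison aimed, by the title of the series, at the development of the immune system. Each group had 2 arrays, low gain from pools of 2 piglets and high gain from pools of 3. Between 32835 and 33972 of 43803 non-control spots lay well above background on each array. Low-gain array a was the noisiest, with a median SD of 0.147 (log2) among repeat spots against 0.0885 to 0.0984 on the other 3 arrays, and the scanner software placed its repeat-spot variation outside its quality range. Over 31471 probes above background on all arrays, the median absolute log2 difference was 0.14 between low-gain arrays and 0.14 between high-gain arrays. Between arrays of different groups it ran from 0.17 to 0.29. Other measures did not separate the groups as clearly. Low-gain array b correlated at 0.99297 with high-gain array b and at 0.99267 with low-gain array a. The shares of probes at least 2-fold apart were 2.72% and 3.31% in these pairs. The high-gain arrays were closest to each other (0.99450 and 2.09%).

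Of the 9 genes past the test when each was read by 1 probe, 5 were higher and 4 were lower in the ileum of low-gain piglets. *BPI*, which encodes a bactericidal protein that binds endotoxin, was 5.48-fold higher in low gain (log2 change 2.45 ± 0.14, SE, n = 2 arrays per group, limma adjusted p = 0.0383). *SAA3*, an acute-phase serum amyloid gene, was 3.77-fold lower (log2 change -1.91 ± 0.10, adjusted p = 0.0326), and *LYZ*, the gene for lysozyme, was 2.87-fold lower (log2 change -1.52 ± 0.10, adjusted p = 0.0467). Genes of cytotoxic lymphocytes had a median log2 change of 0.72 and passed the list test at a preset correlation (camera adjusted p = 3.2e-05). They did not pass with an estimated correlation (adjusted p = 0.76), a test with little power here. Of the 12 members, 1, the granzyme gene *GZMK*, passed over all probes (3.18-fold higher), and 7 passed when the prior variance followed signal intensity. The largest fitted fall among named probes was that of *CA3*, a carbonic anhydrase gene, on 16 of its 19 probes, but its brightest probes did not show it.

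In all, 80 of 33265 probes passed the test, 32 higher and 48 lower in low gain, each with a fitted log2 difference of at least 1.49. Of these 80, 42 had no gene name, and the remaining 38 represented 14 genes. Of the 80 probes, 42 were well above background on all 4 arrays, while 23 were not well above background on either low-gain array and 7 on either high-gain array. For these 30 only a bound can be given, which was at least 2-fold for 28 of them and at least 1.37-fold for the lowest. Taking 1 probe per gene, 5 genes rose and 4 fell among 2158. The number of probes past the test depended on the fit. It was 1250 (751 higher, 499 lower) when the prior variance followed signal intensity and 0 when only probes above background on all 4 arrays were tested, although 6071 of those had an unadjusted p under 0.05 against 6117 in the fit reported here.

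The 5 genes that rose in low gain were led by *LMO1*, which encodes a LIM-domain transcriptional regulator and was 8.11-fold higher (log2 change 3.02 ± 0.10, limma adjusted p = 0.0155). *SFTPD*, which encodes surfactant protein D, a collectin that binds microbial sugars, was 3.65-fold higher (log2 change 1.87 ± 0.10, adjusted p = 0.0323). *CLCA1*, a gene for a secreted goblet cell protein, was 3.31-fold higher (log2 change 1.73 ± 0.10, adjusted p = 0.0393). *GZMK* had a log2 change of 1.67 ± 0.10 (adjusted p = 0.0383). The other probe of *BPI* gave 2.75, and the other 4 probes of *CLCA1* gave 0.71 to 1.95, all in the same direction. *LMO1*, *SFTPD* and *GZMK* had no other tested probe.

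The genes that fell, besides *SAA3* and *LYZ*, were *ABO* and *NR0B1*. *ABO*, which encodes the glycosyltransferase of the blood group antigens, was 7.58-fold lower in low gain (log2 change -2.92 ± 0.12, limma adjusted p = 0.0158). *NR0B1*, an orphan nuclear receptor gene, was 3.92-fold lower (log2 change -1.97 ± 0.10, adjusted p = 0.0323). The other 4 probes of *SAA3* gave log2 changes of -1.94 to -1.81 and the other 2 of *LYZ* gave -1.71 to -1.49, whereas *ABO* and *NR0B1* had no other tested probe. For each of these 9 genes, both arrays of one group lay above both of the other. That was so for 1333 of the 2158 genes (61.8%), where chance gives 33.3%. In the fit reported here, no call among the 9 genes was kept when any 1 of the 4 arrays was left out, but the log2 changes moved by at most 0.15. That shift is set by the gap between the 2 arrays of a group, which a call requires to be small, so it adds no support. The residual degrees of freedom fell from 2 to 1 in the fits without 1 array. The SE, 0.10 to 0.14 across these genes with all arrays, was 0.12 to 0.20, and it rose for each gene except *BPI*, whose SE fell from 0.14 to 0.12 without either high-gain array. With the intensity trend and without low-gain array a, 28 genes were called (21 higher, 7 lower), all 9 among them. None of the 9 calls was kept with no filter on dim probes (adjusted p 0.055 to 0.15), with signal required on all 4 arrays (0.057 to 0.058) or with the letter as a block (0.18 to 0.32), where the log2 changes were the same. None was kept with normexp background correction on the median signal either (adjusted p = 1.0 for each), with *LMO1* at 1.14, *ABO* at -1.26, *BPI* at 1.07, *SFTPD* at 0.89, *GZMK* at 0.55 and *NR0B1* at -0.61. *CLCA1* (1.72), *SAA3* (-1.65) and *LYZ* (-1.41) moved less. In a version of normexp added after the data were seen, with bright backgrounds replaced, all 9 passed. There *LMO1*, *ABO*, *BPI*, *SFTPD*, *GZMK* and *NR0B1* were at 2.12, -2.21, 1.97, 1.59, 1.13 and -1.14. With the mean over a gene's probes, only *ABO*, *BPI* and *LMO1* among the 9 kept their calls, and *CLCA1* was at 1.53.

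**Figure D1:**
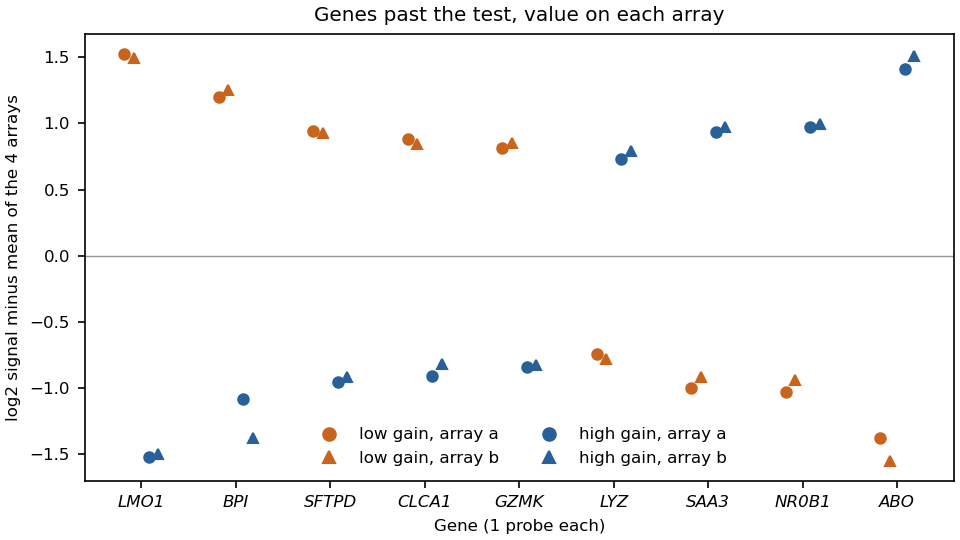
Normalised log2 signal of the 9 genes past the test on each of the 4 arrays, with each gene's mean over the 4 arrays subtracted. Points are single arrays (circles a, triangles b; orange low gain, blue high gain). The low-gain arrays lie above the high-gain arrays for 5 genes and below them for 4.

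*CA3* was chosen for description after its values were seen, because 16 of the 80 probes past the test were its own. All 16 were lower in low gain, with log2 changes of -6.34 to -2.39 (median -5.59, limma adjusted p 0.0102 to 0.0457). For 15 of them the low-gain signal was not well above background on either array, so that only a bound can be given, from at least 5.98-fold to at least 31.7-fold lower. The other 3 of the 19 tested *CA3* probes gave -1.29, -0.49 and 0.27 and did not pass. The last 2 were the brightest of the 19 in both groups, with normalised log2 signals of 0.75 in low gain and 1.24 in high gain for the probe with -0.49 (adjusted p = 0.33), and of 1.49 and 1.22 for the probe with 0.27 (adjusted p = 0.71). They did not show the fall, and *CA3* was therefore not among the genes called from 1 probe each. *ACTA1*, *PHEROC*, *AREG* and *RETN* also each had 1 probe past the test that was not their brightest. The *ACTA1* probe gave 1.54, while its 15 other probes ran from -0.87 to 1.43.

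**Figure D2:**
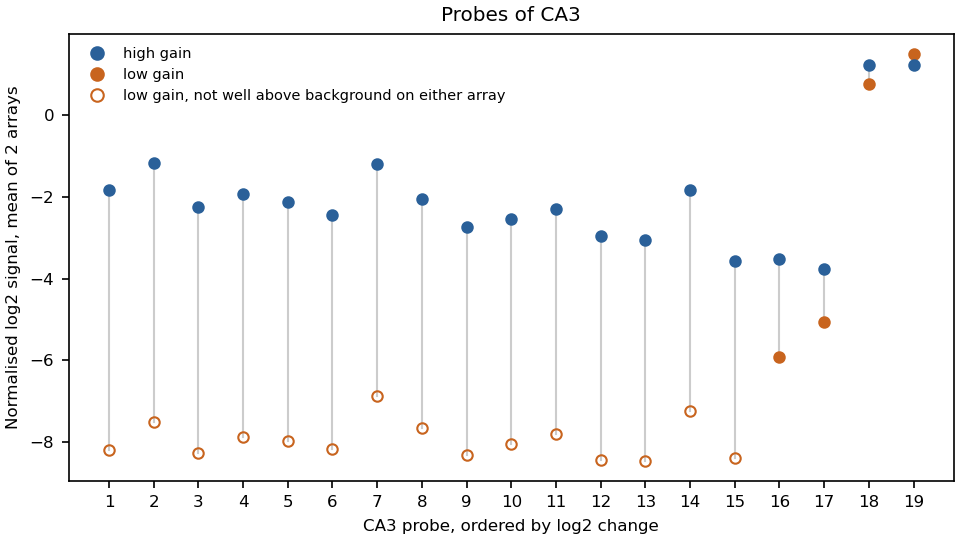
Normalised log2 signal (mean of 2 arrays per group) of the 19 tested CA3 probes, ordered by their log2 change; blue is high gain, orange is low gain, and open circles mark low-gain values not well above background on either array. Of the 19 probes, 18 are lower in low gain and 1 is higher.

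The remaining genes with the largest differences did not pass the test. On the higher side, *CCR3*, an eosinophil chemokine receptor gene, was at least 4.39-fold higher in low gain (adjusted p = 0.0807), *PIWIL1* at least 2.54-fold (adjusted p = 0.166) and *BHMT* at least 1.93-fold (adjusted p = 0.196). None of these 3 was well above background on a high-gain array. *ITIH4*, an acute-phase gene, differed by 1.58 (adjusted p = 0.0597), but its 2 other probes gave 0.16 and 1.35. *RETNLB*, a goblet cell gene, differed by 1.57 (adjusted p = 0.0561), with its other probe at 1.20. *AREG*, a ligand gene of the epidermal growth factor receptor, differed by 1.45, and its other probe, at 1.60, passed. LOC396781, an immunoglobulin heavy chain gene, differed by 1.51 (adjusted p = 0.161), but its 12 other probes ran from -1.51 to 1.82 and 9 of them were higher. On the lower side, *PMAP-23*, a cathelicidin gene, differed by -2.71 (adjusted p = 0.0807). *FABP4*, a fatty acid binding protein of fat cells, differed by -1.55 (adjusted p = 0.0561), with its 5 other probes at -1.60 to -1.35. *TDH* was at least 2.81-fold (adjusted p = 0.178) and *BPIFB1* at least 1.36-fold lower (adjusted p = 0.190), neither being well above background in low gain. *PHEROC* (-1.93), *PLIN1* (-1.63), *SIGLEC1* (-1.57) and *PLEKHD1* (-1.55) had adjusted p-values from 0.122 to 0.257. *PMAP-23*, *PLIN1* and *SIGLEC1* were well above background on 1 of 2 low-gain arrays, and *PLIN1* (0.03) and *BPIFB1* (0.04) changed sign under normexp with bright backgrounds replaced.

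Among the lists fixed in advance, genes of cytotoxic and natural killer (NK) cells shifted towards low gain. Of 12 measured members, 11 had a higher mean in low gain, with a median log2 change of 0.72. The list passed camera's test at the preset correlation (adjusted p = 3.2e-05), but not with an estimated one (adjusted p = 0.76). The correlation estimated for this list was -0.029, and camera's unadjusted p with it was 0.035. No list had an adjusted p below 0.76 in that test, so the value does not set this list apart. *GZMK* rose, and 11 members did not pass over all probes, among them *GZMH* (1.28 ± 0.10), *GZMB* (1.17 ± 0.10) and *GZMA* (0.99 ± 0.10). With the intensity trend, 7 of the 12 rose past the test over all probes and 0 fell. Adjusted over the list alone, 7 members rose, the other 3 being the chemokine genes *CCL5* (0.88) and *XCL1* (0.79) and the receptor gene *KLRK1* (0.65). The second probes of *GZMH*, *GZMB* and *GZMA* gave 1.28, 0.91 and 0.98. *IFNG* (0.11) and *NCR1* (-0.10) lay near 0.

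The other 35 lists tested did not pass, 9 of them with an unadjusted p under 0.05. Goblet cell and mucus genes had a median of 0.46 over 7 members (camera adjusted p = 0.0696), with *CLCA1* up and 6 members not past the test. Adjusted over the list alone, 4 rose, including *RETNLB*, *SPINK4* (0.46) and the goblet cell transcription factor gene *SPDEF* (0.46). Smooth muscle genes had a median of 0.42 over 9 members (adjusted p = 0.0696). None of the 9 passed over all probes, and 5 rose when adjusted over the list alone, including *MYLK* (0.56), *CNN1* (0.48) and *TPM2* (0.45). *DES* differed by 0.51, but its other 2 probes were lower in low gain (-0.34 and -0.02). Both lists passed with the intensity trend (adjusted p = 0.0233 for each), but not with an estimated correlation in the fit without the trend (adjusted p = 0.76 for each).

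Enterocyte and enteroendocrine lists had medians above 0 without passing. Brush-border enzymes had a median of 0.31 over 8 members (camera adjusted p = 0.142), and the peptidase genes *ANPEP* (0.68), *ENPEP* (0.48) and *DPP4* (0.46) rose when adjusted over the list alone. *TMPRSS15* differed by 0.93 with an SE of 0.39. Nutrient transporters had a median of 0.19 over 10 members (adjusted p = 0.135), with *SLC26A3* (0.77), *SLC1A1* (0.57) and *SLC7A9* (0.55) up when adjusted over the list alone, and *SLC3A1* at 0.39. This median turned to -0.03 when all probes of a gene were averaged. Enteroendocrine genes had a median of 0.31 over 11 members (adjusted p = 0.135), and 2 rose when adjusted over the list alone, *CHGB* (0.63, with 14 other probes higher as well) and *SCGN* (0.54). *PCSK1* differed by 0.50 and its other probe by -0.10, while *CHGA* differed by 0.49.

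Lists of other immune cells went in different directions. Macrophage and dendritic cell genes had a median of -0.25 over 12 members (camera adjusted p = 0.135), and *CD1.1* (-1.06) and *CD80* (-0.59) fell when adjusted over the list alone. *CD163*, a scavenger receptor gene of macrophages, differed by -0.41, and *FCGR3A* by 0.36. T cell genes had a median of 0.22 over 14 members (adjusted p = 0.142). When adjusted over the list alone, *CD8A* rose (0.95, its other probe 0.03) and *CD247* fell (-0.67). *FOXP3* (0.94 ± 0.33) and *CD3E* (0.53 ± 0.17) did not pass. Mast cell and eosinophil genes had a median of 0.24 over 5 members (adjusted p = 0.166), with *CCR3* well apart from *GATA2* (0.27), *MCT7* (0.24) and *MS4A2* (0.19). B cell and germinal centre genes had a median of -0.17 over 4 members (adjusted p = 0.379), with *CD79A* at -0.31 and *FCER2* at -0.62. *FCER2* fell when adjusted over the list alone, but was well above background on 1 of 2 low-gain arrays and turned to 0.04 under normexp with bright backgrounds replaced. Neutrophil genes had a median of 0.33 over 10 members (adjusted p = 0.626), and 2 rose and 1 fell when adjusted over the list alone, with *ARG1* at 1.13 and *NCF1* at -1.11.

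Epithelial antimicrobial genes did not move one way. Of 16 members, *BPI* rose, *SAA3* and *LYZ* fell, and 13 did not pass. The list median was 0.22 (camera adjusted p = 0.379). Adjusted over the list alone, 5 rose and 3 fell. The lectin gene *REG3G* (1.06) and the intelectin gene *ITLN2* (1.40) were among those that rose on that count. Complement genes had a median of 0.15 over 16 members (adjusted p = 0.379), which turned to -0.06 when all probes of a gene were averaged, and 4 rose and 1 fell when adjusted over the list alone, with *CFB* at 0.80 and *CLU* at -0.92.

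Cell cycle genes had lower means in low gain for all 8 members, with a median of -0.11 (camera adjusted p = 0.0864). *AURKA* (-0.78) and *CCNB2* (-0.55) fell when adjusted over the list alone, while *TOP2A* (-0.17) and *CDC20* (-0.11) did not. Pattern recognition and NF-kB genes had a median of -0.11 over 19 members (adjusted p = 0.279), with *MYD88* at -1.0 and *RELA* at -0.73 and none past either adjustment. Cytokine and chemokine genes had a median of 0.05 over 31 members (adjusted p = 0.687), with *IL1B* at 0.57 and *TNFSF13* at 0.53. Interferon-stimulated genes had a median of 0.03 over 23 members (adjusted p = 0.951), with *CXCL9* at 0.46 and *BST2* at 0.44. Antigen presentation genes had a median of 0.00 over 21 members (adjusted p = 0.835), with *CD74* at -0.43 and *SLA-7* at 0.36. The medians of these last 3 lists changed sign in at least 1 alternative each.

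**Figure D3:**
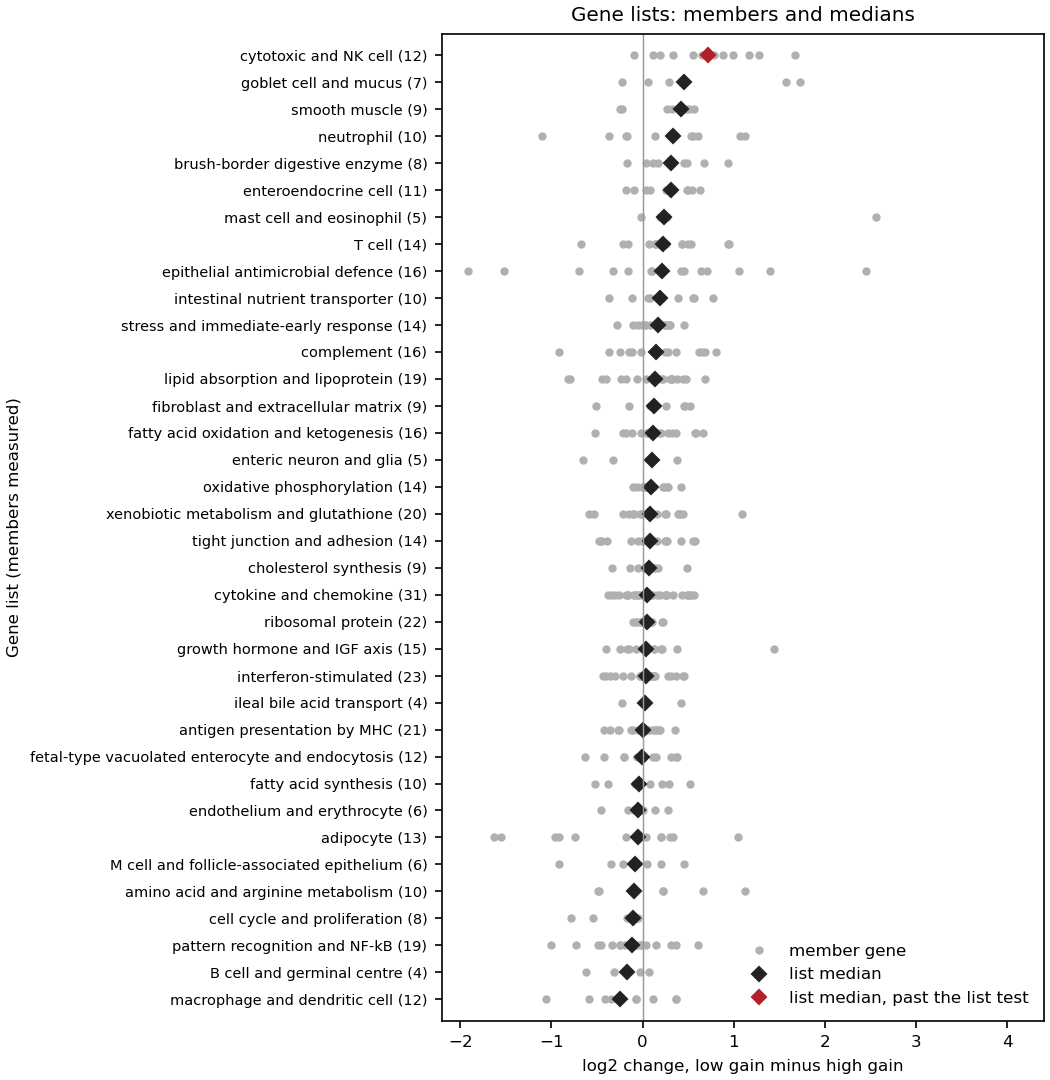
Log2 change (low gain minus high gain) of each measured member (grey) and the median (diamond) of the 36 gene lists tested, with the number of members in parentheses. The cytotoxic and NK cell list (red) has a median of 0.72 and is the list past the test at the preset correlation (adjusted p = 0.76 with an estimated correlation).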

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

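The alternatives with bright backgrounds replaced and with the intensity trend but without low-gain array a were added after the data were seen. All 80 probes kept their direction in every alternative that measured them, and 42 were measured when signal on all 4 arrays was required. Part of this was fixed in advance, since another filter, the intensity trend or the letter block leaves the log2 changes the same. Quantile normalisation called 67 probes (65 shared), median centring 101 (80 shared) and the values deposited by the authors 99 (74 shared). The cause of changes in the counts was not tested unless given here. Low signal limits the size that can be given for many calls, since 23 of the 80 probes were not well above background on either low-gain array.

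No filter on dim probes left 12 probes past the test (3 higher, 9 lower, 12 of at least 2-fold). Requiring signal on all 4 arrays left 0 (0 higher, 0 lower, 0 of at least 2-fold), with 6071 at an unadjusted p under 0.05 in limma. The unadjusted limma p of each of the 9 called genes fell there, to 3.6e-06 to 7.1e-05 from 6.1e-06 to 1.0e-04. Their loss came from the adjustment, since dim probes with small p-values, such as those of *CA3*, were no longer in it. The intensity trend gave 1250 (751 higher, 499 lower, 305 of at least 2-fold, 79 shared), or 60.1% higher against 40% in the fit reported. With the trend and without low-gain array a the numbers were 197, 93 higher, 104 lower and 176 of at least 2-fold, with 71 shared. Normexp on the median signal gave 0 (0 higher, 0 lower, 0 of at least 2-fold) and 0 at an unadjusted p under 0.05 in limma. The 9 called genes kept their direction there, but their SE, 0.10 to 0.14 in the fit reported, was 0.91 to 1.14 and some changes shrank, with *LMO1* at 1.14 (3.02 in the fit reported), *ABO* at -1.26 (-2.92), *BPI* at 1.07 (2.45), *SFTPD* at 0.89 (1.87), *GZMK* at 0.55 (1.67) and *NR0B1* at -0.61 (-1.97). On low-gain array a and high-gain array b, 22 and 25 spots had a local background above 100, up to 166072. With these replaced by the array's median, normexp called 850 (496 higher, 354 lower, 147 of at least 2-fold, 67 shared), or 58.4% higher. All 9 genes then passed, with *LMO1* at 2.12, *ABO* at -2.21, *BPI* at 1.97, *SFTPD* at 1.59, *GZMK* at 1.13 and *NR0B1* at -1.14. In the alternatives without normexp, the log2 changes of the 9 genes stayed within 0.20 of the fit reported. The letters did not pair the arrays, since the deviations of same-letter arrays correlated at -0.03 across probes. The replicate block gave 0 (0 higher, 0 lower, 0 of at least 2-fold), with 4703 at an unadjusted p under 0.05, and it leaves fewer degrees of freedom. Counts of at least 2-fold in this part are of fitted differences, bounds included.

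Leaving out 1 array, which leaves 1 array in a group that is assumed to vary like the others, gave 0 to 37 probes (0 to 5 higher, 0 to 33 lower, 0 to 37 of at least 2-fold). The numbers were 36 without low-gain array a, 37 without b, 0 without high-gain array a and 0 without b, the last 2 with 3071 and 5662 at an unadjusted p under 0.05 in limma. The number of lists past the test, 1 in the fit reported, was 1 to 2 without 1 array, 3 with normexp, 3 with normexp and bright backgrounds replaced, 3 with the trend, 4 with the mean over a gene's probes and 0 with an estimated correlation. The lists that joined were goblet cell, smooth muscle and cell cycle genes. The cytotoxic list was past the test in the 15 alternatives with the preset correlation, with medians from 0.34 to 0.77 and adjusted p from 1.1e-06 to 0.00174.

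List medians that reversed lay near 0 after the reversal, but not all lay near 0 in the fit reported. There, nutrient transporters were at 0.19, stress genes at 0.17, complement at 0.15 and fatty acid oxidation at 0.12. With quantile normalisation, antigen presentation gave -0.035 and bile acid transport -0.037. With median centring, vacuolated enterocyte genes gave 0.016. With normexp on the median signal, antigen presentation gave -0.0063 and cytokines -0.0028. With bright backgrounds replaced, adipocyte genes gave 0.030, antigen presentation -0.026 and fatty acid synthesis 0.073. The deposited table gave -0.032 for antigen presentation, 0.052 for fatty acid synthesis and -0.013 for tight junctions. The mean over probes gave -0.020 for antigen presentation, -0.013 for cholesterol synthesis, -0.057 for complement, -0.034 for fatty acid oxidation, -0.016 for interferon-stimulated genes, -0.030 for nutrient transporters and -0.00075 for stress genes. Each of these lists had a median above 0 in the fit reported, so all reversals by the mean over probes went downwards, and their cause was not tested. Without 1 array, the medians ran from -0.16 to 0.017 for M cell genes, -0.11 to 0.093 for amino acid metabolism, -0.057 to 0.15 for enteric neurons and glia, -0.052 to 0.060 for fatty acid synthesis and -0.039 to 0.063 for vacuolated enterocytes. They ran from -0.047 to 0.095 for bile acid transport, -0.035 to 0.092 for interferon-stimulated genes and -0.0018 to 0.080 for ribosomal proteins. With the trend and without low-gain array a, fatty acid synthesis gave 0.060, vacuolated enterocytes 0.063, bile acid transport -0.047 and M cell genes 0.017.

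Among the named genes, *SOX10* (-0.030) and *PPARA* (-0.011) reversed with normexp on the median signal. *PLIN1* (0.030), *BPIFB1* (0.037) and *FCER2* (0.037) reversed with bright backgrounds replaced. *ACSS2* (-0.039) and *CA3* (-4.69) reversed with the mean over probes, as the brightest probe of each differs in sign from its others. For 15 of the 19 *CA3* probes the low-gain signal was not well above background, so that -4.69 is a fitted value and no measured size. Without 1 array, *SOX10* ran from -0.064 to 0.82 and the brightest *CA3* probe from -0.23 to 0.77, and with the trend and without low-gain array a they gave -0.064 and -0.23. Of the other gene values under alternatives, 1372 kept their side of the threshold (889 higher, 483 lower), 89 passed it newly (61 higher, 28 lower) and 78 lost it (43 higher, 35 lower).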

Other observations

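All the tests of explanations in this part were chosen after the results they bear on had been seen.

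None of the metabolic lists passed the test. Oxidative phosphorylation had a median of 0.09 over 14 members (camera adjusted p = 0.379), with *CYCS* at 0.43 and *SDHD* at 0.28. Fatty acid oxidation had a median of 0.12 over 16 members (adjusted p = 0.525), with *PPARA* at 0.66 ± 0.45 and the coactivator gene *PPARGC1A* at 0.59, which rose when adjusted over the list alone. Fatty acid synthesis had a median of -0.03 over 10 members (adjusted p = 0.951), with *FADS2* at -0.52 and *ACSS2* at 0.52, and cholesterol synthesis 0.07 over 9 (adjusted p = 0.835), with *CYP51* at 0.48 and *HSD17B7* at -0.33. Lipid absorption had 0.14 over 19 members (adjusted p = 0.888), with *APOE* at -0.81 and *DGAT2* at -0.79. Amino acid metabolism had -0.09 over 10 (adjusted p = 0.999), although the urea cycle genes *ARG1* (1.13) and *OTC* (0.66) rose when adjusted over the list alone. Xenobiotic metabolism had 0.09 over 20 (adjusted p = 0.613), with the glutathione peroxidase gene *GPX3* at 1.09 and *SULT1A3* at -0.59. The growth hormone and IGF list had 0.04 over 15 members (adjusted p = 0.835), with *AREG* at 1.45 and *HBEGF* at -0.40.

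The remaining structural, epithelial and housekeeping lists did not pass either. Tight junction genes had a median of 0.08 over 14 members (camera adjusted p = 0.613), with *CDH1* at 0.58 and *CLDN3* at 0.55, both up when adjusted over the list alone. Fibroblast and matrix genes had 0.12 over 9 (adjusted p = 0.379; *SPARC* 0.52, *THY1* -0.51), endothelium and erythrocyte genes -0.05 over 6 (adjusted p = 0.808; *CLDN5* -0.46, *ENG* 0.28) and enteric neurons and glia 0.11 over 5 (adjusted p = 0.951; *SOX10* 0.38). Genes of the vacuolated enterocytes of the newborn gut had -0.0059 over 12 (adjusted p = 0.951; *CTSZ* -0.63). M cell genes had -0.09 over 6 (adjusted p = 0.687; *CLU* -0.92, *PGLYRP1* 0.45) and bile acid transport genes 0.02 over 4 (adjusted p = 0.951; *NR1I2* 0.42, *NR1I3* -0.22). Stress genes had 0.17 over 14 (adjusted p = 0.379; *TXNIP* 0.46, *HSPA6* 0.30) and ribosomal protein genes 0.05 over 22 (adjusted p = 0.808; *RPS15* 0.23, *RPL14* 0.22). Of lists too small to test, the plasma cell and immunoglobulin list had 3 members (LOC396781 1.51, *PIGR* 0.34, *XBP1* 0.25), crypt stem cells 2 (*ASCL2* 0.53, *SOX9* 0.40) and the circadian clock 1 (*ARNTL* 0.28).

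The cytotoxic and NK cell list had a median log2 change of 0.72 and passed at the preset correlation. With an estimated correlation, camera's adjusted p was 0.76, the lowest of any list in that test, and the unadjusted p was 0.035. That test has 2 degrees of freedom and could hardly pass any list, so its outcome decides little. Over all probes, 11 of the list's 12 members did not pass in the fit reported, whereas 7 of the 12 rose past the test with the intensity trend. The noise of low-gain array a did not account for the shift, as the list median was 0.76 without that array, against 0.72 with it. Scaling did not account for all of it, since the list passed under each of 5 scalings and background corrections at the preset correlation. The lowest median was 0.34, with normexp on the median signal, so background treatment may account for part of its size. More immune cells of every kind would also raise macrophage genes, whose median was -0.25. Their changes differed from those of the cytotoxic list in a permutation test across genes (p = 0.00017). Genes are not independent and both lists were picked after their values were seen, which limits this p. B cell genes were at -0.17, but neutrophil (0.33), mast cell and eosinophil (0.24) and T cell (0.22) medians lay above 0. A rise of several kinds of immune cell therefore stays open. A difference in cytotoxic lymphocytes linked to weight gain may remain as a hypothesis, untested, because litter, sampling site along the ileum and single piglets in the pools cannot be separated from the group in this design.

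Large changes of single genes were seen between the pools. The log2 changes of the 9 called genes moved by at most 0.15 when any 1 array was left out. This does not argue for the changes, since a call already requires a small gap between the arrays of a group. Those fits leave 1 residual degree of freedom. A misreading by 1 probe was argued against for the 4 called genes with other probes, where 100% of 11 other probes had the same sign. This does not cover a related gene read by all probes, which stays possible for *SAA3* and *LYZ*. Nor does it cover genes such as *ACTA1*, whose called probe was not its brightest. For the 5 called genes with no other probe it stays open. For *CA3*, it stays open whether the 2 brightest probes read another transcript or the 16 that passed read a part that is missing from its transcript in low gain, as the binding sites were not examined. Fat on the high-gain slices is a candidate source of *CA3* transcript, which fat and muscle cells hold, and *FABP4* (-1.55), *ADIPOQ* (-0.96), *AQP7* (-0.92) and *CIDEA* (-0.75) were lower too. The adipocyte list as a whole had a median of -0.05 over 13 members and a camera adjusted p of 0.379 (3 down and 1 up when adjusted over the list alone), with *RETN* (1.04) and *CIDEC* (0.30) higher, so this could be neither excluded nor shown, and a genotype of a piglet in a small pool, for *ABO* above all, was not tested.

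Goblet cell, enteroendocrine, brush-border and smooth muscle lists had medians above 0 and proliferation and macrophage lists below 0 in low gain minus high gain, without passing the list test. Of the other epithelial lists, antimicrobial genes (0.22) and tight junction genes (0.08) also had medians above 0, vacuolated enterocytes (-0.0059) and M cell genes of the epithelium over follicles (-0.09) did not, and the nutrient transporter median (0.19) turned to -0.03 when all probes of a gene were averaged. The tight junction, M cell and vacuolated enterocyte medians also changed sign in at least 1 alternative each. A lower share of lymphoid follicle in the low-gain slices might give this, since it would raise markers of all other cell types alike. For 6 lists of such types, with means from -0.05 to 0.62, a permutation test of unequal shifts across genes gave p = 0.0808. The macrophage list was taken out of that test after its result was seen, because follicles also hold macrophages and dendritic cells, and with it p was 0.0013. With a B cell list of 4 members at -0.17, a different tissue make-up of the slices cannot be told apart from a difference within cells.

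The 4 arrays can be split into pairs in 3 ways, so that no share under 0.05 is possible and chance cannot be judged from them. The real split gave 80 probes and was the 1 split with as many, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 6117 probes and the others 745 and 816.

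The deposited log2 table holds values below 0 on low-gain array a (34, down to -12.6) and high-gain array b (39, down to -11.9), and none on the other arrays. Of these, 20 and 23 lie at spots with a local background above 100 in the scanner files.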
